A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

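Genomic DNA of fission yeast was measured on 8 Agilent 2-colour comparative genomic hybridization arrays. Per the labels' protocols, cells were held for 6 h at 18 °C, released at 32 °C and treated with 6 mM hydroxyurea, which slows DNA synthesis by lowering nucleotide supply. Each array compared DNA labelled as time 80, S phase, with DNA labelled as time 0, unreplicated, of the same strain; the unit of time is not given in the sources used here. There were 2 strains with 2 replicates each, and each replicate was hybridized on 2 arrays with the dyes exchanged. Replicate 1 of both strains was labelled with Alexa 555 and Alexa 647, and replicate 2 with Cy3 and Cy5. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

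The deposited intensity values came from Agilent Feature Extraction 10.7.3.1, per the file headers. The processed red and green intensity of each spot was background-subtracted, spatially detrended and multiplied by 1 linear dye factor per channel, with no lowess, per the file headers. Each array held 42641 probes of 45 to 60 bases on chromosomes I, II and III, and 66 mitochondrial probes. Coordinates are those of the array design, which the file headers call Spombe:NCBI:Feb2002.

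From these values, log2 ratios of S phase over time 0 DNA were computed with the sign taken from the dye labels. Control spots were left out, and so were outlier spots, which made up 0.290% to 4.73% of the probes per array. Each array was centred on the median of its chromosomal probes, with no loess or quantile step, since most probes of a copy number array can shift one way. A value of 0 therefore marks the median DNA, not unreplicated DNA. The 2 arrays of a replicate were averaged and counted as 1 replicate, so n = 2 per strain. Probes were averaged in 1 kb bins by their midpoint, with a median of 4 probes per bin, and 12125 bins had a value in all 4 replicate profiles.

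Bins, origins and genes were tested with limma 3.58.1 in R 4.3.3 on the 4 replicate profiles with strain as the only term and Benjamini-Hochberg adjustment at 0.05. Origins were called with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 as peaks of the running mean over 5 bins, with a prominence of 0.1 on the log2 scale, a height of 1.1-fold and a distance of at least 5 bins. Widths were taken at 0.5 of the prominence. The joint map holds the peaks of the mean of both strains' profiles, and the value of an origin is the mean of the 5 bins at its summit. Sharing was set at 3 kb and compared with 1000 circular shifts within each chromosome in a one-sided permutation test. Feature classes and gene lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation. Gene values are means of at least 2 probes with midpoints inside the gene. For the strain genotype, the mean log2 signal of both channels was used, each channel centred on its median. Bounds written as "at least N-fold" set the brighter strain against the lowest signal among probes well above background on each array and channel, without loess or quantile steps.

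The reference annotation was of another assembly, ASM294v3. Probe length falls with GC content in this design, so the coordinates were compared with the reference by the correlation of probe length and reference GC content in 50000 bp windows. The best shift lay within 10 bp of 0 in 75 of the 75 windows of chromosome I up to position 3750000 and in 138 of the 139 windows of chromosomes II and III. In none of the 36 windows of chromosome I to the right of that position did it lie there, and the median shift was 6150 bp. Gene names, centromere spans, AT content and the mating-type region were therefore used only on chromosomes II and III and on chromosome I up to that position. The 1 window of II and III that did not match, from 1600001 to 1650000 on II with 40 probes and a best shift of -1929 bp, was kept. It holds the centromere of II, 9 of the 11 centromere bins and 2 joint-map origins, so annotation there was not supported by this comparison. The 6063 probes to the right, 14.2% of the chromosomal probes, have coordinates but no annotation here, and the centromere of chromosome I was not run as a class member.

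Named loci were chosen by a rule set before the data were examined, as were the tests, classes, 9 gene lists and most alternatives. The rule took the 10 highest joint-map origins past the threshold and above 0 in every replicate, and up to 5 origins higher and up to 5 lower in rad3del by size of the difference. It added landmarks, and the highest and lowest pair of each gene list. Origins are named by their 1 kb bin and the nearest protein-coding gene on each side. The alternatives were a normexp background correction with an offset of 50, loess, another centring point, a filter on dim probes, scaling, single dye orientations, a GC correction, a replicate block, other bin widths, other peak settings and leaving out each replicate. The files hold median spot signals, so normexp ran on medians and not on means as first written. Masking spikes and undetected DNA, which left out 308 bins and 9 joint-map origins, and a list of heat shock genes were chosen after seeing the data.

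Replicate numbers go with the dye chemistry in both strains, which makes them a shared batch. The main tests left this pairing out, and it entered only in the replicate block and in the paired permutation test. The deviations of same-numbered replicates from their strain means correlated at 0.46 over bins and 0.35 over origins. Replicate 1 of both strains shared slide 1, and replicate 2 of each strain had a slide of its own. A fit with slide as a block, fixed or random, left no residual degrees of freedom, so values within slide 1 are given instead.

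The steps were tested on simulated data. Of 100 bins changed by 0.2 on the log2 scale among 12125, the comparison between strains recovered 3, and of 100 changed by 0.5 it recovered 71, with 0 false calls. With the replicate block it recovered 0 and 0. The simulated noise was independent between replicates, without the shared deviations of same-numbered replicates. These counts therefore do not measure the recovery in the real profiles, with or without the block. Peak calling found 58 of 58 simulated origins. The simulated origins were tall and evenly spaced on a flat base, so low or crowded peaks were not tested. Median spot signals lay 46.9 to 86.0 times above the local background in green and 50.0 to 82.2 times in red.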

Results

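The study mapped where DNA synthesis starts in 2 strains of the fission yeast Schizosaccharomyces pombe released from a cold block into hydroxyurea. The strain nda3-km311 carries a cold-sensitive allele of nda3, the beta-tubulin gene, which arrests cells in mitosis in the cold. The other strain, rad3del nda3-km311 (rad3del below), also lacks rad3, which encodes the kinase of the DNA damage and replication checkpoint (ATR in mammals). Each strain had 2 replicates, and each replicate was the mean of 2 dye-exchanged arrays. Values are log2 ratios of S phase DNA over time 0 DNA, given as mean ± SD with n = 2 per strain, where 0 is the median of the array.

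DNA of rad3 was not detected in the rad3del strain over most of the gene. Of 33 probes inside rad3, 25 were not well above background on any rad3del array and were well above it on every nda3-km311 array. These probes ran from 904607 to 911534 on chromosome II, and their signal was at least 21.5-fold lower in rad3del. The 6 probes further right in rad3 gave signal in rad3del, apart from 1 that stood at -3.61 in replicate 2. The annotated span of swi1, a replication fork protection gene, overlaps rad3 and holds part of the same stretch. Only this bound is given, since a difference taken against signal at the background has no exact size.

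A stretch of chromosome III was not detected in nda3-km311. From 1494160 to 1499165, beside and in the flocculin gene pfl4, 15 of 20 probes were not well above background on any nda3-km311 array and were well above it on every rad3del array. Their signal was at least 29.5-fold lower in nda3-km311.

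Both strains gave a profile of separate peaks over all 3 chromosomes. Among the highest joint-map origins, apart from the spikes described below, the bin from 1604001 to 1605000 on II, between rpb1 and yox1 in the span given for the centromeric non-coding RNAs, had 0.54 ± 0.12 in nda3-km311 and 0.46 ± 0.13 in rad3del. The bin from 3498001 to 3499000 on I, between rps502 and shd1 and within 5 kb of a spike, had 0.53 ± 0.048 and 0.47 ± 0.0071, and the bin from 1265001 to 1266000 on II, between rtn1 and but2, had 0.51 ± 0.059 and 0.49 ± 0.033. On chromosome III, the bin from 574001 to 575000 on III in asp1, an inositol pyrophosphate kinase gene, had 0.51 ± 0.036 and 0.50 ± 0.027, the bin from 1416001 to 1417000 on III between sec5 and lmb1 had 0.50 ± 0.014 and 0.51 ± 0.020, and the bin from 1687001 to 1688000 on III in tef3, a translation elongation factor gene, had 0.50 ± 0.046 and 0.48 ± 0.011. In the part of chromosome I used without annotation, the bin from 3873001 to 3874000 on I had 0.51 ± 0.039 and 0.52 ± 0.021 and the bin from 3754001 to 3755000 on I had 0.50 ± 0.062 and 0.47 ± 0.099. The 3 probes of ura4, which lies beside a known cluster of origins on chromosome III, averaged 0.36 ± 0.050 and 0.33 ± 0.0085. Of 12125 bins, 4688 lay above baseline in nda3-km311 and 4505 in rad3del (limma, adjusted p under 0.05). Of 179 joint-map origins, 176 passed above 0 in both strains, with a median spacing of 46 kb. These origins were chosen as peaks above a set height in the mean of the same profiles. The count of those that passed is therefore no independent test that they lie above 0. Bin counts depended on the zero point, and centred on the 20th percentile 8048 and 7665 bins passed.

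**Figure D1:**
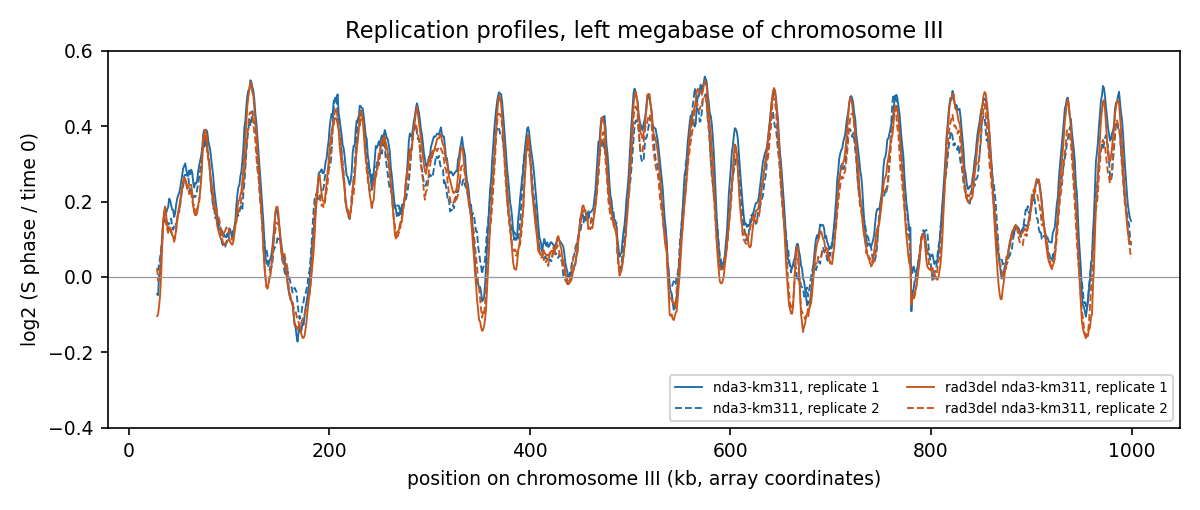
Running mean over 5 bins of the log2 ratio of S phase over time 0 DNA (y axis) along the left megabase of chromosome III (x axis, kb in array coordinates), with 1 line per replicate. The 4 lines rise and fall at the same places, and the tallest peaks reach about 0.5.

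More origins were called in rad3del than in nda3-km311, with 216 in its mean profile against 153. Chromosome I had 92 against 56, II had 61 against 44, and III had 63 against 53. Single replicates gave 174 and 146 in nda3-km311 and 233 and 205 in rad3del (exact permutation test, two-sided p = 0.333, the smallest p that 2 against 2 can give). With same-numbered replicates kept as pairs, rad3del had 59 more in each pair (exact paired permutation test, two-sided p = 0.5, the smallest that 2 pairs can give). Of the nda3-km311 origins, 140 of 153 had a rad3del origin within 3 kb, against a mean of 20.5 and a highest of 63 in 1000 shifted maps (one-sided permutation p = 0.001, the smallest they can give). Between the replicates of nda3-km311 the count was 111 of 174, and between those of rad3del 194 of 233. For single replicates of the 2 strains, 164 and 154 of 174 origins of nda3-km311 replicate 1 lay near one of rad3del replicates 1 and 2. For nda3-km311 replicate 2 it was 122 and 125 of 146. Such counts depend on the number of origins in the map searched, so they do not rank strains against replicates. The 76 rad3del origins without a nda3-km311 origin within 3 kb had a median height of 0.20, against 0.34 over all rad3del origins. With smoothing over 9 bins the counts were 139 in nda3-km311 and 158 in rad3del. The median width of the called peaks was 19.6 kb in nda3-km311 and 14.3 kb in rad3del. In single replicates, over their peaks within 3 kb of a joint-map origin, it was 18.7 and 16.9 kb against 15.1 and 15.9 kb, with no test.

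**Figure D2:**
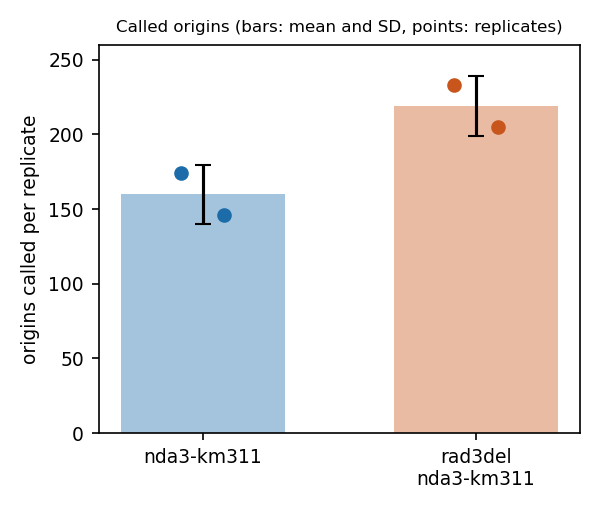
Origins called per replicate (y axis) in each strain (x axis), with bars for the mean of 2 replicates, error bars for their SD and points for the replicates. The nda3-km311 replicates had 174 and 146 origins and the rad3del replicates 233 and 205.

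Of 179 joint-map origins, 3 differed between the strains, and all 3 were lower in rad3del. The bin from 1949001 to 1950000 on II lay in lsd90, with 1.29 ± 0.50 in nda3-km311 and 0.24 ± 0.0096 in rad3del, a difference of -1.04 (SE 0.12, adjusted p = 2.1e-06). The bin from 2060001 to 2061000 on III lay in npp106 beside ssa2, a heat shock protein 70 gene, with 0.84 ± 0.30 and 0.23 ± 0.012, a difference of -0.61 (SE 0.085, adjusted p = 2.8e-05). The bin from 205001 to 206000 on II lay in wwm2, with 0.49 ± 0.66 and -0.16 ± 0.0060, a difference of -0.65 (SE 0.15, adjusted p = 0.016). The wwm2 mean rested on replicate 2 of nda3-km311, at 0.96 against 0.027 in replicate 1, and at this joint-map origin the difference without nda3-km311 replicate 2 was -0.18, adjusted p = 0.0067. With origins called anew in that setting wwm2 was not among those that passed. The highest lsd90 probe stood at 1.65 and 3.23 in the nda3-km311 replicates and the highest ssa2 probe at 1.11 and 2.18, above the value of 1 that a doubling over the median would give. Tests were limma with adjustment over all origins, and 7 origins had an unadjusted p under 0.05. Within slide 1 the 3 differences were -0.70, -0.40 and -0.19. With the replicate number as a block wwm2 did not pass (adjusted p = 0.080). None of the 3 passed with normexp, at -1.15, -0.38 and -0.51 (adjusted p = 0.17 to 0.70), nor with scaled replicates or with S phase DNA in red only (adjusted p = 0.16 to 0.99). The lost signal of rad3 did not pass with normexp either, so normexp cannot by itself decide on these calls. With S phase DNA in green only, lsd90 (-1.12, adjusted p = 5.4e-05) and npp106 (-0.65, adjusted p = 0.00028) passed among the origins called on those arrays, but at the origins of the joint map none of the 3 did (adjusted p = 0.062 to 0.71).

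**Figure D3:**
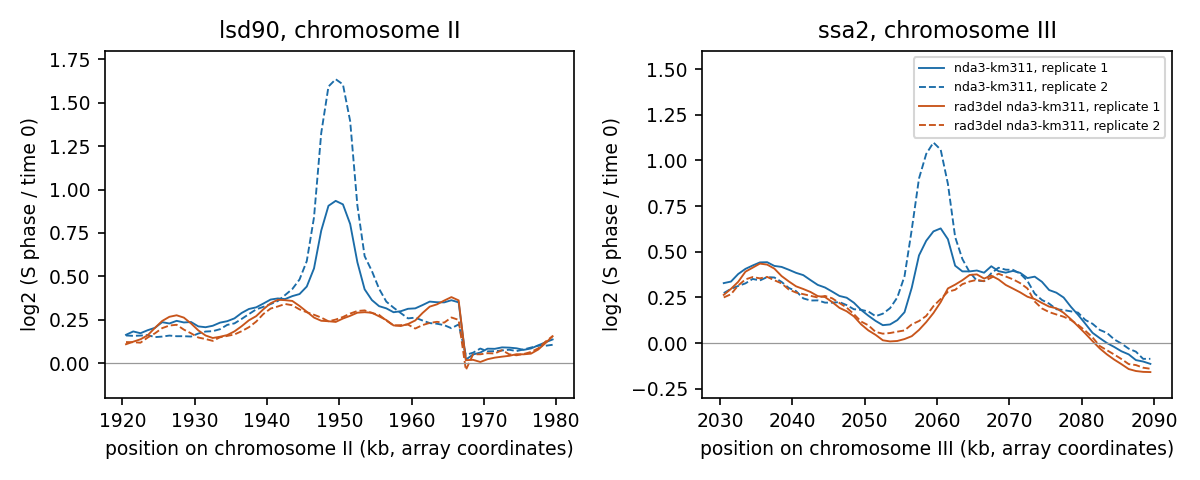
Running mean over 5 bins of the log2 ratio of S phase over time 0 DNA (y axes) around lsd90 on chromosome II and ssa2 on chromosome III (x axes, kb in array coordinates), with 1 line per replicate. The nda3-km311 lines rise at both genes. The rad3del means at these joint-map origins are 0.24 and 0.23, below other rad3del peaks in the spans shown, which reach 0.35 and 0.40.

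Other named origins did not pass between strains. The next largest negative differences were -0.38 at 1498001 on III beside pfl4, on DNA not detected in nda3-km311, and -0.088 at 1604001 on II at the centromere. The largest positive differences were 0.13 in SPAC11D3.03C at 111001 on I (0.075 ± 0.0070 and 0.20 ± 0.0050), 0.12 in cpc2, the RACK1 gene, at 2440001 on I (0.16 ± 0.10 and 0.29 ± 0.078), 0.12 at 3286001 on II (0.087 ± 0.0089 and 0.21 ± 0.033), 0.12 in tgs1 at 842001 on I (0.10 ± 0.030 and 0.22 ± 0.0032) and 0.11 at 4733001 on I (0.091 ± 0.050 and 0.20 ± 0.014). Without nda3-km311 replicate 1, 9 of the origins called anew passed, among them cpc2 (0.19, adjusted p = 0.0015). Without nda3-km311 replicate 2, 5 of the origins called anew passed, among them the bin at the centromere of II (-0.17, adjusted p = 0.021) and the bin beside pfl4 (-0.79, adjusted p = 4.7e-35), where the lone nda3-km311 sample was taken to vary like the rad3del samples.

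Of 12125 bins, 1 differed between the strains. This bin, from 1494001 to 1495000 on III in pfl4, had a difference of -0.45 (limma, adjusted p = 0.027). All 4 of its probes lie in the stretch not detected in nda3-km311, so the difference rests on undetected DNA, and 0 bins passed with the filter on dim probes or with masking (limma, 1137 and 1093 with an unadjusted p under 0.05). In the main comparison 1146 bins had an unadjusted p under 0.05. With the replicate number as a block, 577 bins differed, 465 higher in rad3del and 112 lower. Without nda3-km311 replicate 1 the count was 1239 and without its replicate 2 it was 592, where the spread came from the rad3del replicates alone; without either rad3del replicate it was 0 (limma, 304 and 525 bins with an unadjusted p under 0.05). Over bins, which are not independent, the strain difference within slide 1 and that of replicate 2 correlated at 0.49.

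The order of origin heights was similar in the strains apart from the spikes. Across 179 joint-map origins, which are not independent, the strain means had Pearson's r = 0.64 and Spearman's rho = 0.87, and outside masked regions r was 0.96. Replicates had r = 0.70 within nda3-km311 and 0.96 within rad3del. Without nda3-km311 replicate 1, the replicate with the lower spikes at lsd90 and ssa2, the strain correlation was 0.27. The SD of the smoothed profile was 0.21 ± 0.024 in nda3-km311 and 0.19 ± 0.0046 in rad3del, a ratio of 0.908 (exact permutation test, two-sided p = 0.667, where the smallest possible is 0.333). Within slide 1 the ratio was 0.855.

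**Figure D4:**
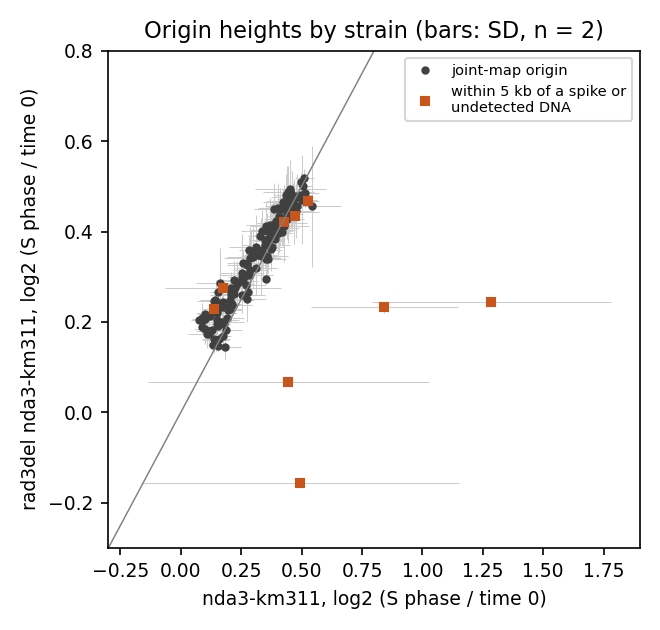
Height of the 179 joint-map origins in nda3-km311 (x axis) and rad3del nda3-km311 (y axis), as log2 ratios of S phase over time 0 DNA with SD bars (n = 2) and the line of equal values. Squares mark origins within 5 kb of a spike or of undetected DNA. The other origins lie near the line, with 129 of 170 above it.

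Chromosome ends differed from each other. The left end of I, its first 100 kb, had -0.27 ± 0.020 in nda3-km311 and -0.17 ± 0.011 in rad3del, the right end of I -0.16 ± 0.015 and -0.064 ± 0.034, the left end of II -0.32 ± 0.018 and -0.24 ± 0.052, and the right end of II -0.24 ± 0.027 and -0.17 ± 0.0064. The ends of III lay above 0, with 0.21 ± 0.022 and 0.18 ± 0.0028 on the left and 0.13 ± 0.0075 and 0.10 ± 0.0026 on the right. The centromere of II had 0.28 ± 0.14 and 0.21 ± 0.085 over 26 probes and that of III 0.13 ± 0.14 and 0.057 ± 0.061 over 7. Array coordinates around the centromere of II did not match the reference, so the bin at 1604001 and 9 of the 11 centromere bins below carry an unsupported annotation. The mating-type region had 0.0085 ± 0.0074 and -0.046 ± 0.0063. As classes of bins, all calls below were made at the preset correlation of camera. With an estimated correlation none of the 8 classes passed in either strain (adjusted p = 0.36 to 0.99 in nda3-km311 and 0.48 to 0.92 in rad3del, with 1 and 0 classes at an unadjusted p under 0.05). The ends of I and II were low (means -0.24 and -0.16, adjusted p = 6.0e-24 and 6.5e-15, and 0.36 and 0.55 with the estimated correlation) and the ends of III high (0.16 and 0.13, adjusted p = 4.9e-11 and 2.5e-08). Here and between the strains, camera set the ends against all bins, not against the rest of their own chromosomes. A high level of chromosome III as a whole was therefore not separated from one of its ends. The 124 bins with a tRNA gene had 0.16 and 0.19 (adjusted p = 7.8e-05 and 4.8e-07), and the 11 centromere bins 0.27 and 0.19 (adjusted p = 0.0027 and 0.016). The 649 bins without a protein-coding gene had 0.064 and 0.096 and passed in rad3del (adjusted p = 0.0056) but not in nda3-km311 (adjusted p = 0.093, and 0.034 with the replicate block).

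Sequence content classes did not pass in the single strains. The 25% of bins with the highest AT content had 0.019 and 0.051 (camera, adjusted p = 0.98 and 0.13), and in nda3-km311 their median, -0.00058, and the direction of the test were opposite in sign to the mean. With the replicate block these bins passed in rad3del at the preset correlation (adjusted p = 0.033). The 25% with the lowest AT content had 0.041 and 0.019 (adjusted p = 0.093 and 0.58), with a median of -0.011 in rad3del. The 18 bins of the mating-type region had -0.0017 and -0.054 (adjusted p = 0.98 and 0.16), with an upward test direction in nda3-km311. Relative to all bins with annotation, leaving out 1 replicate made calls of the lowest AT bins in nda3-km311 (without nda3-km311 replicate 1, 0.058, adjusted p = 0.00041), of bins without a protein-coding gene in nda3-km311 (without nda3-km311 replicate 2, 0.076, adjusted p = 0.0020) and of the highest AT bins in rad3del (without rad3del replicate 2, 0.049, adjusted p = 0.0080; without nda3-km311 replicate 1 or 2, 0.033, adjusted p = 0.033), and ended that of the centromeres in rad3del (without rad3del replicate 1, 0.13, adjusted p = 0.059).

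Between the strains, all 8 classes passed in camera at the preset correlation and none with an estimated correlation (adjusted p = 0.27 to 0.64, with 0 classes at an unadjusted p under 0.05). The ends of I and II were higher in rad3del by 0.085 (adjusted p = 3.2e-29, 0.27 with the estimated correlation, and 0.11 within slide 1), and each of the 4 ends was higher, by 0.072 to 0.097. The ends of III were lower by 0.027 (adjusted p = 3.2e-05, and -0.035 within slide 1), the centromeres by 0.076 (adjusted p = 0.0016, and -0.11) and the mating-type region by 0.053 (adjusted p = 0.00022, and -0.045). The bins with a tRNA gene were higher by 0.033 (adjusted p = 0.0022, and 0.015 within slide 1) and those without a protein-coding gene by 0.032 (adjusted p = 6.6e-05, and 0.023). The highest and lowest AT bins differed by 0.032 and -0.022, but by 0.021 and -0.0022 within slide 1. Relative to all bins with annotation, both AT classes, at 0.029 and -0.025 (adjusted p = 1.0e-09 and 2.9e-07), changed sign without nda3-km311 replicate 2 (-0.0012 and 0.0070), as did tRNA bins (-0.014), and the centromeres did so without nda3-km311 replicate 1 (0.0060). The calls on bins without a protein-coding gene ended without nda3-km311 replicate 2 (0.0025, adjusted p = 0.83), on the lowest AT bins (-0.0088, adjusted p = 0.11) and tRNA bins (0.0069, adjusted p = 0.39) without rad3del replicate 1, and on the centromeres without rad3del replicate 2 (-0.033, adjusted p = 0.13). With the GC correction the highest AT bins (-0.0032, adjusted p = 0.67), the lowest (0.00053, adjusted p = 0.72), bins without a protein-coding gene (-0.0023, adjusted p = 0.72) and tRNA bins (0.0012, adjusted p = 0.94) did not pass, nor did the centromeres with normexp (-0.027, adjusted p = 0.33). The GC correction takes out the trend of the ratio with GC content, so the AT classes came near 0 by construction.

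Genes of the fixed lists lay both above and below baseline in both strains. Among histone genes 2 of 5 measured members were above baseline, htb1 with 0.49 ± 0.0029 and 0.48 ± 0.012 in nda3-km311 and rad3del and hta1 with 0.47 ± 0.032 and 0.48 ± 0.059, and 1 was below, pht1, the H2A.Z gene, with -0.061 ± 0.017 and -0.13 ± 0.012. The value of hht2 was -0.0092 ± 0.094 and -0.020 ± 0.049. Of 23 origin licensing and firing genes, 5 were above and 10 below in both strains, from mcm3, of the replicative helicase, with 0.40 ± 0.058 and 0.38 ± 0.013, and orc4, of the origin recognition complex, with 0.32 ± 0.049 and 0.29 ± 0.041, to orc1 with -0.26 ± 0.034 and -0.27 ± 0.039 and sld5 with -0.27 ± 0.038 and -0.28 ± 0.043. Of 15 spindle and mitosis genes, 5 were above and 7 below in both strains, from mad1, of the spindle checkpoint, with 0.42 ± 0.087 and 0.45 ± 0.041, and the separase gene cut1 with 0.41 ± 0.056 and 0.41 ± 0.018 to the tubulin gene nda2 with -0.27 ± 0.049 and -0.20 ± 0.014 and cut9 with -0.28 ± 0.029 and -0.22 ± 0.010. The mutated gene nda3 had -0.18 ± 0.10 and -0.19 ± 0.032. Of 8 checkpoint genes, 3 were above and 4 below in nda3-km311, and 4 above and 3 below in rad3del. The rad3del count above includes rad3 (0.058) and swi1 (0.099), whose ratios rest on DNA not detected in rad3del. The kinase gene chk1 had 0.41 ± 0.073 and 0.37 ± 0.035 and rad9 0.20 ± 0.033 and 0.13 ± 0.056, while swi3 had -0.17 ± 0.0051 and -0.19 ± 0.032 and rad4 -0.18 ± 0.052 and -0.21 ± 0.0062. Of 13 replication fork genes, 4 were above in both strains, 9 below in nda3-km311 and 6 in rad3del, with cdc27 at 0.15 ± 0.075 and 0.17 ± 0.0067, ssb2 at 0.18 ± 0.061 and 0.11 ± 0.014, rfc1 at -0.16 ± 0.047 and -0.16 ± 0.031 and spp2 at -0.26 ± 0.037 and -0.25 ± 0.022. Without nda3-km311 replicate 2, pht1 lost its call in nda3-km311 (-0.049, adjusted p = 0.14) and hht2 gained 1 (-0.076, adjusted p = 0.023), and pht1 also lost it without rad3del replicate 1 or 2 (-0.061, adjusted p = 0.12). In rad3del, rad9 lost its call without rad3del replicate 1 (0.089, adjusted p = 0.14), and ssb2 without rad3del replicate 1 or 2 (0.12, adjusted p = 0.071 and 0.098, adjusted p = 0.12). With the GC correction pht1 did not pass in nda3-km311 (-0.038, adjusted p = 0.11).

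The smaller fixed lists also held genes on both sides of baseline. Of 4 nucleotide supply genes, 1 was above baseline in both strains, hal3, listed as tds1, with 0.22 ± 0.010 and 0.17 ± 0.038, and 3 were below, suc22 of ribonucleotide reductase with -0.21 ± 0.080 and -0.091 ± 0.033, ddb1 with -0.27 ± 0.013 and -0.23 ± 0.035 and cdt2 with -0.28 ± 0.068 and -0.27 ± 0.0061. Of 6 cohesin genes, 1 was above and 3 below in nda3-km311 and 2 above and 4 below in rad3del, from rad21, the kleisin subunit, with 0.37 ± 0.0067 and 0.39 ± 0.033 and psm3 with 0.043 ± 0.0026 and 0.082 ± 0.016 to psc3 with -0.26 ± 0.039 and -0.23 ± 0.036 and eso1 with -0.31 ± 0.022 and -0.28 ± 0.023. Of 8 heterochromatin genes, 4 were above and 0 below in nda3-km311 and 3 above and 1 below in rad3del, with the deacetylase gene clr3 at 0.31 ± 0.024 and 0.34 ± 0.022, swi6 at 0.16 ± 0.097 and 0.13 ± 0.047, clr4 at 0.0052 ± 0.015 and -0.063 ± 0.014 and chp1 at -0.031 ± 0.018 and -0.042 ± 0.0034. Of 5 forkhead and Rif1-type timing genes, 1 was above and 1 below in both strains, with the phosphatase genes sds21 at 0.21 ± 0.0071 and 0.19 ± 0.012 and dis2 at 0.013 ± 0.0063 and 0.073 ± 0.018, taz1 at -0.020 ± 0.0041 and 0.0061 ± 0.0075 and fkh2 at -0.13 ± 0.028 and -0.10 ± 0.014. Calls in rad3del ended without rad3del replicate 1 for swi6 (0.099, adjusted p = 0.15), and without rad3del replicate 1 or 2 for suc22 (-0.067, adjusted p = 0.30 and -0.11, adjusted p = 0.089), psm3 (0.071, adjusted p = 0.22 and 0.094, adjusted p = 0.11), clr4 (-0.053, adjusted p = 0.35 and -0.073, adjusted p = 0.20), fkh2 (-0.092, adjusted p = 0.12 and -0.11, adjusted p = 0.066) and dis2 (0.086, adjusted p = 0.14 and 0.060, adjusted p = 0.29). Normexp ended the rad3del calls of suc22 (-0.099, adjusted p = 0.066), clr4 (-0.079, adjusted p = 0.064) and dis2 (0.037, adjusted p = 0.29), and with the GC correction psm3 passed in nda3-km311 (0.064, adjusted p = 0.018).

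No gene list stood apart among the 8244 genes measured. In each strain and between them, 0 of 9 lists passed (camera at the preset correlation, adjusted p = 0.55 to 0.83, 0 lists with an unadjusted p under 0.05; adjusted p = 0.76 to 0.84 with an estimated correlation). Mean and median differed in sign for checkpoint genes in nda3-km311 (0.012 and -0.044) and between strains (0.0096 and -0.021), and in rad3del for histone genes (0.16 and -0.0028) and spindle genes (0.0089 and -0.098). Between strains 0 of 8244 genes passed (limma, 909 with an unadjusted p under 0.05), and 0 of 85 members of the fixed lists did, 6 of them with an unadjusted p under 0.05. Adjusted over the list alone, the ratios of rad3 (higher in rad3del by 0.13, adjusted p = 0.031) and swi1 (0.12, adjusted p = 0.038) passed, both on DNA not detected in rad3del. Counts above and below baseline were over all genes tested; adjusted over the list alone they were equal, except for heterochromatin, with 3 above in nda3-km311 and 0 below in rad3del.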

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

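The tests of explanations for the spikes and for the undetected stretch of chromosome III were chosen after these patterns were seen, the one on heat shock genes before its own value was seen and the others after.

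The joint-map origins at lsd90 (difference -1.04), beside ssa2 (-0.61) and at wwm2 (-0.65) were singled out because the strains differed in a test, all higher in nda3-km311. Pooled over 6 spike loci, S phase DNA carried a share of -0.020 of the strain difference (jackknife SE 0.21). The jackknife was chosen knowing that the SD over loci, 0.80, would leave extra S phase DNA open, so the pooled share does not settle it. At lsd90, ssa2 and wwm2 the shares were 0.20, -0.50 and -0.071, with the rest in less time 0 DNA in nda3-km311. Over all loci the shares ran from -1.13 to 1.15, with hob1 at 0.54 and shd1 at 1.15 the other way. At 2 loci, lsd90 and ssa2, the spike stood on all 4 nda3-km311 arrays, which argues against 1 dye orientation as the source there. A loss of time 0 DNA at heat shock genes in general was not seen. For 12 such genes other than ssa2, the mean time 0 level of nda3-km311 minus rad3del was 0.089, against 0.021 on average in 10000 random lists. This lay at percentile 94.3, toward more time 0 DNA in nda3-km311. Why time 0 DNA of these loci may have been low in nda3-km311, and whether Rad3 has a part in it, was not tested.

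The bin from 1494001 to 1495000 on chromosome III (difference -0.45) was singled out by the same kind of test. All 4 of its probes were not well above background on any nda3-km311 array, so the difference rests on undetected DNA. The stretch was found by its 15 probes not well above background on any nda3-km311 array, and 100% of them were well above background on all rad3del arrays, a value known when the test was written, which argues against probes that are dim in themselves. Of 329 other spots printed within 2 rows and 2 columns of these, 0% (0 spots) were likewise not well above background on any nda3-km311 array, which argues against a damaged patch. That the strains differ in sequence here stays open and was not tested.

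Feature classes were singled out because the strains differed in camera at a preset correlation. The differences, rad3del minus nda3-km311, were 0.085 at the ends of I and II, -0.027 at the ends of III, -0.076 at the centromeres, 0.032 in the 25% of bins with the highest AT content, -0.022 in the 25% with the lowest, -0.053 in the mating-type region, 0.032 in bins without a protein-coding gene and 0.033 in tRNA bins (adjusted p = 0.27 to 0.64 with an estimated correlation, where none passed).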

How the results depend on the processing

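Masking was chosen after seeing the data; the other alternatives were planned. The direction of the amplitude ratio, the numbers of origins called and the number shared stayed on their side or within 1.5 times under every alternative run on them. For origins called, this limit is wider than the gap between the strains, 216 against 153. It therefore does not test whether that gap holds, and the gap was smaller with smoothing over 9 bins. The cause was not tested except where the construction shows it. Masking took out the DNA of the bin and the origins called in the main comparison, so those calls could not be made with it. Bins differing between strains numbered 0 with normexp, the filter on dim probes, the 20th percentile, S phase DNA in red only or in green only, masking, single probes or 3 kb bins, 0 to 1239 leaving out 1 replicate, 577 with the replicate block and 336 with the replicate block and GC correction (limma, 304 to 2665 at an unadjusted p under 0.05 where 0 passed). The replicate block also ended the call at wwm2 and made those of bins without a protein-coding gene in nda3-km311 and of the highest AT bins in rad3del, and changed no other call. Origins differing numbered 0 with normexp, scaling, red only, masking or smoothing over 3 bins (limma, 8 to 45 at an unadjusted p under 0.05), 1 with smoothing over 9 bins or a window of 1 bin, 5 with the 20th percentile and 3 to 9 leaving out 1 replicate. Bins above baseline were 8048 and 7665 (nda3-km311, then rad3del) with the 20th percentile, and, by construction of the bins, 14327 and 13659 of single probes and 1704 and 1643 of 3 kb bins.

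Origin width in nda3-km311 was 17.7 kb with normexp, 17.4 with loess, 18.7 with GC correction, 16.9 with the 20th percentile, 16.2 in green only, 18.9 and 20.6 with smoothing over 3 and 9 bins, 16.9 and 21.5 with prominence 0.05 and 0.2, and 17.9 to 19.6 leaving out 1 replicate. In rad3del it was 11.5 kb with the 20th percentile, 16.9 in red only, 11.0 in green only, 10.9 and 18.5 with smoothing over 3 and 9 bins, and 12.3 and 16.6 with prominence 0.05 and 0.2. The height correlation was 0.87 with normexp, 0.81 with the 20th percentile, 0.96 with masking and 0.27 to 0.78 leaving out 1 replicate. Masking leaves the spikes out by construction. The log2 signal difference over all rad3 probes, most of them at the background in rad3del, was -5.17 and passed. With normexp it was -1.03, not past the threshold, so its size depends on the background step and only the bound is used. Normexp thus did not call DNA that was at least 21.5-fold lower over 25 of the 33 probes. The loss of a call under normexp therefore cannot by itself decide on that call.

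Of 8 feature classes, 3 passed in rad3del and 4 between strains with GC correction, where the right end of chromosome I was left out, 4 to 7 between strains leaving out 1 replicate, and 0 in each comparison with an estimated correlation in camera (1, 0 and 0 at an unadjusted p under 0.05). Turned strain differences, relative to all bins, were -0.0032 and 0.00053 for the highest and lowest AT bins and -0.0023 for bins without a protein-coding gene with GC correction. For the AT classes this follows from the correction, which takes out the trend with GC content. Leaving out 1 replicate, the highest AT bins ran from -0.0012 to 0.059, the lowest from -0.057 to 0.0070, tRNA bins from -0.014 to 0.073 and the centromeres from -0.16 to 0.0060. Slide could not be fitted as a block, and scaling fixes the amplitude ratio by construction, so neither was run. Signal over background was high on all arrays, so dim spots limit few values.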

Other observations

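The heat shock list and the tests in this part were chosen after the results they follow up were seen and before their own values were.

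Heat shock genes, listed because of the spike at ssa2, lay both above and below baseline. Of 12 measured genes, 6 were above and 4 below in both strains, from sks2 with 0.36 ± 0.0010 and 0.35 ± 0.012 in nda3-km311 and rad3del and hsp10 with 0.36 ± 0.032 and 0.41 ± 0.0016 to ssa1 with -0.23 ± 0.11 and -0.26 ± 0.011 and hsp16 with -0.31 ± 0.018 and -0.13 ± 0.041. Between strains 0 passed over all genes (limma, 909 genes in all with an unadjusted p under 0.05). Adjusted over the list alone, hsp16 was higher in rad3del by 0.17 (adjusted p = 0.021) and psi1 differed by -0.14 (adjusted p = 0.027).

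Low origins stood higher in rad3del. Outside masked regions, the 85 lower-ranked joint-map origins had a mean of 0.21 in nda3-km311 and 0.26 in rad3del, a mean difference of 0.045 with 74 higher in rad3del, against 0.011 and 55 of the 85 upper-ranked; the prediction did not say that masked origins were left out, and with them the lower 89 had 0.034, with 76 higher. The smaller SD of rad3del lowers positive heights, so scaling replicates to the same SD raises the difference at positive heights whatever its cause. With it the difference was 0.068 (SE 0.0040 over origins, which are not independent), and 0.051 for the upper-ranked. The prediction that it would fall could therefore not come true, and this test cannot decide on a smaller amplitude around the median. A smaller amplitude around a level above the low origins, which would raise them, was not tested. Centred on the 20th percentile the difference was 0.022 (SE 0.0042 over origins), and -0.012 for the upper-ranked, since this step moves all origins of a profile alike. Within slide 1, with 1 profile per strain, it was 0.024 (SE 0.0045 over origins), and -0.0012 for the upper-ranked. These SEs do not measure the spread between replicates. For the size of the difference, the centring point and the slide cannot be told apart from an effect of the strain, which was not tested further.

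Mitochondrial probes gave median log2 ratios that went with the dye. In nda3-km311 they were 0.59 and 0.80 with S phase DNA in Alexa 647 or Cy5, and -0.024 and -0.25 with it in Alexa 555 or Cy3. In rad3del they were 0.49 and 0.21, and 0.028 and 0.078.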
